A study of Mus musculus with 18 samples.

How the data were processed

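The arrays measured mRNA of sorted splenic NK cells from 6-week-old WT and Runx3 KO mice injected with complexes of interleukin-15 and its receptor alpha chain; per the labels, RNA was amplified for the Mouse Gene 1.0 ST array. The authors made the deposited log2 values by RMA, with Partek as the other tool named in the submitters' notes; the notes give no versions, and the log2 scale was judged from the range of the values. The deposited table was used as it stands, with 1 column per array and no filter on low values. Of its probe sets, 21789 have 1 gene symbol in the annotation table used here, 1621 have several and 11989 are not listed there; the latter 2 kinds were tested and counted but not named. The symbols of 21698 probe sets whose gene identifier is in the reference gene table were checked and were equal in all 21698.

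Samples were grouped by subset and genotype into 6 groups of 3 arrays. The depth of an array is not a count; the median SD within groups was 0.14 log2 over probe sets. With limma 3.58.1 in R 4.3.3, a linear model with 1 mean per group was fitted to all 18 arrays (12 residual degrees of freedom, 2.18 prior degrees of freedom), moderated by eBayes and tested by contrasts: KO against WT in each subset and averaged over subsets, DP against CD27, CD11b against DP and CD11b against CD27 in WT, and CD11b against CD27 in KO. The interaction of genotype and subset was tested by a moderated F test. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over all probe sets, and an adjusted p under 0.05 is called passing. Folds are given with 95% intervals from the moderated standard error. A permutation of 3 against 3 arrays cannot give a two-sided p under 0.1, so the moderated test was used for single genes as well.

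For gene lists, each gene was represented by the probe set with the highest mean (19938 genes, 999 of them with several probe sets). Of the 568 genes of 23 lists, covering NK cell genes, signalling, the cell cycle and markers of other cell types, 515 had a probe set. Lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation and with fry; members were counted over all probe sets and when adjusted over the list alone. The named genes are Runx3, Runx1, Cbfb, Cd27, Itgam, Ncr1, Tbx21 and Eomes, then per comparison the 10 largest rises and 10 largest falls among genes that pass with arrays that do not overlap, up to 4 members of a list with the largest changes among those that pass (2 where none does), and the 10 smallest p-values of the F test; predicted genes, histone genes and olfactory receptors could be passed over. Runx2 was on the list but no probe set carries its symbol alone. The members named under the T cell list, Cd74, Lyz2, Xist and Eif2s3y are marker genes of the lists. Comparisons, tests, lists, this rule and most alternatives were fixed before the data were examined.

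Alternatives were cyclic loess normalization, probe sets above the median mean (6.33), an intensity trend with a robust prior (statmod 1.5.0), a fit of the compared groups alone, array weights, no moderation, a 1.5-fold minimum, 1 probe set per gene, the replicate number as a fixed or random block, and each array left out in turn; where 2 arrays remained in a group, they were assumed to vary like the other groups. Chosen after the data were examined were Xist as a covariate, leaving out the 3 arrays of KO replicate 3, and averaging the 3 arrays of a sample before comparing 3 samples with 3. Whether replicate numbers pair the arrays was checked by correlating deviations from group means: within KO the 3 same-numbered pairs gave r of 0.213 to 0.642 and pairs with other numbers a median of -0.363 to -0.299, the WT CD11b arrays paired with DP and CD27 (0.218 to 0.456), the WT CD27 and DP arrays did not in each number (0.440, 0.139 and -0.0094), and WT arrays did not pair with KO arrays.

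The procedure was tested on simulated data with 200 changed genes and the spread of these arrays. Of genes changed 2-fold, 82.5% were recovered in the CD27 comparison, 84.5% in DP, 82.5% in CD11b, 92% in the average and 86% in WT CD11b against CD27; at 1.5-fold the shares were 56.5%, 51.5%, 51.5%, 79.5% and 52.5%. The F test recovered 186 of 200 genes changed 4-fold in 1 subset, with 7 other calls. A simulated shifted list of 24 genes, the mature NK markers, was recovered by camera at an adjusted p of 3.25e-21, with 1 other list called. Of the 24 genes 15 are shared with other lists, so the other call may hold shifted genes. Errors were drawn independently for each gene and each array, so the simulation does not test lists whose genes vary together. Nor does it test dependence between arrays with the same replicate number (correlation 0.206 within a genotype). That dependence bears on the average over subsets and on comparisons between subsets.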

Results

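Gene expression was measured on 18 arrays of sorted splenic natural killer (NK) cells from mice injected with interleukin-15 bound to its receptor alpha chain, a complex that activates and expands NK cells. The mice were wild type (WT) or Runx3 knockout (KO). Runx3 is a transcription factor of the Runt family. NKp46+ cells were sorted into immature CD27+CD11b- cells (called CD27 here), CD27+CD11b+ double-positive cells (DP) and CD27-CD11b+ cells (CD11b). The 3 subsets and 2 genotypes gave 6 groups of 3 arrays. Log2 values ran from 3.91 to 14.97 and Pearson's r between arrays from 0.960 to 0.995. The median SD within groups was 0.14 log2, and the number of arrays limits the precision of every value below. The labels do not state whether arrays with the same replicate number came from the same animals, so the p-values measure a spread between samples that may not be independent.

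The marker genes of the sort followed the gates in both genotypes. Cd27 averaged 11.79 ± 0.10 (log2, mean ± SD, n = 3) in WT CD27 cells and 9.87 ± 0.06 in WT CD11b cells. Itgam, which encodes CD11b, was the reverse and averaged 10.14 ± 0.77 and 12.60 ± 0.03. Ncr1, which encodes NKp46, lay between 13.58 and 13.75 in all 6 groups. Runx3 itself was lower in KO arrays of each subset. Its means were 10.93 ± 0.21 in KO and 11.45 ± 0.05 in WT CD27 cells, 10.84 ± 0.08 and 11.48 ± 0.10 in DP cells, and 11.27 ± 0.18 and 11.76 ± 0.12 in CD11b cells. It was 1.43-fold lower in CD27 (adjusted p = 0.0416), 1.55-fold lower in DP (adjusted p = 0.0175) and 1.40-fold lower in CD11b cells (adjusted p = 0.0416). The 3 KO arrays lay below the 3 WT arrays each time. With 1 array left out these adjusted p-values reached 0.162 (without CD27 WT replicate 2), 0.103 (without DP WT replicate 3) and 0.191 (without CD11b WT replicate 2). The average over subsets passed at an adjusted p of 0.000116, but not when the arrays of a sample were first averaged (adjusted p = 0.101). Where the probe set lies relative to the deleted part of the gene is not known here, so this value checks the genotype labels only weakly. Xist was low, between 5.13 and 5.69, on the arrays of WT replicate 1 and KO replicates 1 and 2, and between 12.48 and 13.00 on the others. The Y-linked gene Eif2s3y was between 6.44 and 9.10 on the arrays of WT replicate 2 and KO replicate 3, against 11.02 to 11.15 on the arrays with low Xist. Xist thus differed between replicate numbers and was not balanced between the genotypes. With high Xist and an intermediate Eif2s3y signal, WT replicate 2 and KO replicate 3 cannot be assigned to 1 sex from these values.

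**Figure D1:**
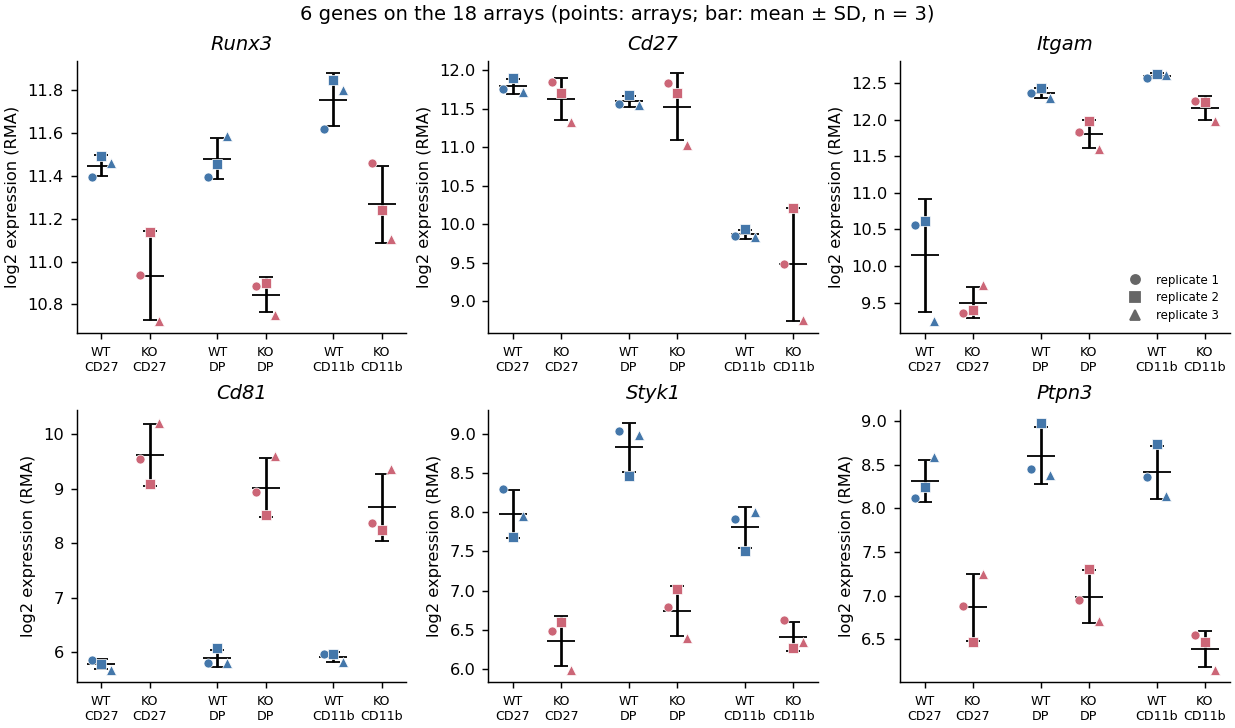
Log2 expression (RMA) of 6 genes on each of the 18 arrays, with WT in blue and KO in red; symbols give the replicate number and bars the mean ± SD of 3 arrays. Cd81 is higher, and Runx3, Styk1 and Ptpn3 are lower, on each KO array than on each WT array of the same subset, whereas Cd27 and Itgam follow the sorted subset.

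The comparison of KO with WT immature CD27 cells asked which genes depend on Runx3 in this subset. KO cells had more mRNA of Cd81, a tetraspanin, by 14.4-fold (95% interval 9.02 to 22.9, adjusted p = 6.37e-05), and of the C-type lectin receptor Clec4e by 5.84-fold (4.30 to 7.92, adjusted p = 6.37e-05). Gzmb, which encodes granzyme B, rose by 4.15-fold (3.01 to 5.70, adjusted p = 0.000375). Other rises were those of the granzyme inhibitor family member Serpinb9b, 8.36-fold higher (5.4 to 13.0, adjusted p = 0.000267), and the ectonucleotidase Entpd1 (CD39), 4.15-fold higher (2.83 to 6.08, adjusted p = 0.00161). The genes that fell included the cell adhesion molecule Dscam, 4.82-fold lower (3.81 to 6.11, adjusted p = 2.92e-05), the receptor Gpr25, 4.82-fold lower (2.89 to 8.04, adjusted p = 0.00583), and Gzmm, which encodes granzyme M, 3.24-fold lower (2.25 to 4.66, adjusted p = 0.00418).

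In CD27 cells 321 probe sets passed, 91 higher and 230 lower in KO, and these represent 69 named genes higher and 172 lower (148 and 172 of 320 probe sets after cyclic loess). The count was 117 without CD27 WT replicate 2 and 14 when only the 2 groups compared were in the fit. All 321 had KO and WT arrays that did not overlap. Chance gives this for 10% of unselected probe sets, but passing the test nearly requires it, so it adds no evidence. Further named genes that rose were the receptor F2rl2 (log2 change 2.08), the phosphatase Dusp1 (2.08), the mitotic genes Ccnb2 (2.93) and Prc1 (2.32), and Rgl1 (2.15). Other falls were those of the potassium channel Kcnc1 (-2.03), Clip4 (-2.01), the receptor Crtam (-1.95), Serpina4-ps1 (-1.71), Serpina5 (-1.63) and the kinase-like Styk1 (-1.62). The T cell receptor component Cd3e had a change of -3.00 (adjusted p = 0.0179).

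Mature NK markers rose as a list in CD27 KO cells, with a median of 0.29 log2 over 24 genes (camera adjusted p = 4.57e-07; adjusted p = 0.520 with an estimated correlation). Of these, 4 rose, 0 fell and 20 did not pass, and 7 rose when adjusted over the list alone. The 4 were Entpd1, the protease Cma1 (2.27-fold higher), the transcription factor Prdm1, known as Blimp-1 (2.15-fold higher), and Gzma, which encodes granzyme A (1.35-fold higher). Among 19 cytotoxic effectors 4 rose, Gzmb, Serpinb9 (1.69-fold higher) and Serpinb6b (1.40-fold higher) included, 1 fell, Gzmm, and 14 did not pass (camera adjusted p = 0.110). Adjusted over the list alone, 5 rose and 3 fell. Cytokine and chemokine receptors had a median of -0.10 over 31 genes. Of these 3 fell, Il4ra (2.94-fold lower), Il21r (2.87-fold lower) and Ifnar2 (1.28-fold lower), 0 rose and 28 did not pass. With p-values adjusted over the list alone, 2 rose and 8 fell (camera adjusted p = 0.0292; adjusted p = 0.637 with an estimated correlation). Of the 23 lists 6 passed in CD27 cells with the preset correlation and 0 with an estimated correlation. Lists of other cell types were among them: erythroid and platelet markers had a median of 0.13 with 0 of 19 called (camera adjusted p = 0.0111; adjusted p = 0.698 with an estimated correlation). Mast cell and basophil markers had a median of 0.09 (camera adjusted p = 0.0408; adjusted p = 0.620 with an estimated correlation). Of these 20 only Cma1 rose, a gene also on the list of mature NK markers, and 1 rose when adjusted over the list alone. T cell markers had a median of -0.35 over 16 genes. Of these Cd3e and Cd3d (2.50-fold lower) fell, 0 rose and 14 did not pass, with the same 2 when adjusted over the list alone (camera adjusted p = 0.00353; adjusted p = 0.175 with an estimated correlation). Without the 3 arrays of KO replicate 3, mature NK markers (median 0.34, camera adjusted p = 1.45e-06) and T cell markers (-0.26, 0.000872) still passed. Cytokine and chemokine receptors (-0.03, 0.0662), erythroid and platelet markers (0.02, 0.989) and mast cell and basophil markers (0.07, 0.114) did not.

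Cell cycle genes had a median KO-WT difference of 1.13 log2 over 53 genes in CD27 cells (camera adjusted p = 3.70e-13; adjusted p = 0.698 with an estimated correlation). Of the 53, Ccnb2 alone rose, 0 fell and 52 did not pass, and 1 rose when adjusted over the list alone. The arrays of KO replicate 3 stood far above the others. Without the 3 arrays of this replicate the median was 0.37 and 8 genes rose. Cd74, a gene of antigen-presenting cells, read 7.86 on the CD27 array of KO replicate 3, against at most 6.32 on WT CD27 arrays.

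In CD27 cells 14 of the 20 genes named for the size of their change kept their call under each alternative run for them. Alternatives run for single genes were cyclic loess, the intensity trend with a robust prior, the random block and leaving out arrays. For KO against WT, Xist as a covariate was run as well. The fit of the compared groups alone, array weights and the remaining alternatives were not run for single genes. Ccnb2, Prc1, Rgl1, Cd3e, Crtam and Serpina5 lost it with 1 array left out. Their adjusted p-values were up to 0.146, 0.0587, 0.173 and 0.0587 for Ccnb2, Prc1, Rgl1 and Crtam (without WT replicate 2), 0.0812 for Cd3e (without KO replicate 1) and 0.0823 for Serpina5 (without KO replicate 2). The same holds for the list members Cd3d, Il4ra, Il21r, Ifnar2, Serpinb6b and Cma1, at up to 0.154, 0.0870, 0.0892, 0.101, 0.0605 and 0.109.

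The same question was asked in DP cells, the intermediate subset. Cd81 was 8.78-fold higher in KO (95% interval 5.51 to 14.0, adjusted p = 0.000497), Clec4e 7.88-fold higher (5.81 to 10.7, adjusted p = 2.33e-05). The MAP kinase phosphatase Dusp1 was 5.21-fold higher (3.64 to 7.47, adjusted p = 0.000506). The imprinted gene Mest was 5.20-fold higher (3.46 to 7.82, adjusted p = 0.00112). The activating receptor Cd226 (DNAM-1) was 2.50-fold higher (2.02 to 3.10, adjusted p = 0.000811). Falls were led by Clip4, 5.82-fold lower (4.32 to 7.86, adjusted p = 7.63e-05), and Styk1, 4.26-fold lower (3.07 to 5.91, adjusted p = 0.000647). Also lower were Kcnc1, 4.02-fold lower (3.02 to 5.35, adjusted p = 0.000363), and the phosphatase Ptpn3, 3.06-fold lower (2.18 to 4.30, adjusted p = 0.00532).

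Altogether 140 probe sets passed in DP cells, 60 higher and 80 lower in KO (43 and 63 named genes). The count was 46 without DP WT replicate 2 and 17 when only the 2 groups compared were in the fit. Further rises were those of Prc1 (log2 change 2.48), the schlafen family gene Slfn1 (2.20), Lrrn4 (2.19), the cytokine Il10 (1.93), Tmem176b (1.83) and the inflammasome gene Nlrp1a (1.76). Further falls were those of the lipase Mgll (-1.88), the annexin Anxa8 (-1.82), the transcription factor Gata6 (-1.70), the glycosyltransferase Galnt3 (-1.61), C1ql3 (-1.60) and Pdlim1 (-1.45).

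Gene lists moved little in DP cells apart from the cell cycle, whose median was 1.43 log2 over 53 genes (camera adjusted p = 7.20e-20; adjusted p = 0.894 with an estimated correlation). None of the 53 passed over all probe sets by limma, at adjusted p-values of 0.0551 for Ccnb2 and 0.132 for Ccna2, and 4 rose when adjusted over the list alone. Without the 3 arrays of KO replicate 3 the median was 0.52 and 15 genes rose. Cd74 read 8.58 on the DP array of that replicate, against at most 5.23 on WT DP arrays. Markers of ILC1-like cells, which are innate lymphocytes related to NK cells, had a median of 0.07 over 25 genes. Of these Tmem176b and Inpp4b (2.64-fold higher) rose, 0 fell and 23 did not pass (camera adjusted p = 0.0442, or 0.389 with an estimated correlation). With the replicate number as a fixed block this list did not pass. Adjusted over the list alone, 6 rose. Mature NK markers had 0 calls among 24 and a median of 0.09 (camera adjusted p = 0.138), and the 2 lists above were those that passed with the preset correlation.

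Leaving out 1 array ended the calls of 11 of the 20 DP genes named for their size. These were Prc1, Mgll, Slfn1 and Pdlim1 at adjusted p-values of up to 0.0697, 0.0643, 0.0940 and 0.0688 and Anxa8 at 0.214 (without WT replicate 2). The others were Lrrn4 and Tmem176b at 0.110 and 0.232 (without WT replicate 3), Il10 and Galnt3 at 0.102 and 0.0952 (without KO replicate 3), and Gata6 and C1ql3 at 0.121 and 0.0591 (without KO replicate 1). The call of Inpp4b ended as well, at 0.0612 (without KO replicate 1).

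In the most mature subset, CD11b cells, falls were among the largest changes. The kinase gene Nuak1 was 9.51-fold lower in KO (95% interval 7.66 to 11.8, adjusted p = 6.85e-08) and Anxa8 9.86-fold lower (5.8 to 16.8, adjusted p = 0.000403). The transcription factor Gata6 was 6.48-fold lower (4.12 to 10.2, adjusted p = 0.000474) and the integrin chain Itgb4 5.29-fold lower (3.61 to 7.77, adjusted p = 0.000384). Rises included Clec4e, 6.99-fold higher (5.15 to 9.48, adjusted p = 1.78e-05), and Cd81, 6.69-fold higher (4.2 to 10.7, adjusted p = 0.000474). Mest was 5.26-fold higher (3.50 to 7.90, adjusted p = 0.000474) and Dtx1, a regulator of Notch signalling, 3.82-fold higher (2.79 to 5.24, adjusted p = 0.000415). Receptors of NK cells changed in both directions: Cd226 was 2.68-fold higher (adjusted p = 0.000231) and the checkpoint receptor Tigit 2.98-fold higher (adjusted p = 0.000122). Cd96 was 2.17-fold lower (adjusted p = 0.000951) and the interleukin-18 receptor gene Il18r1 2.4-fold lower (adjusted p = 0.000408).

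In CD11b cells 457 probe sets passed, 161 higher and 296 lower in KO (104 and 231 named genes; 234 and 266 of 500 probe sets after cyclic loess). The order of the subsets by number of calls depends on the fit: with array weights CD27 cells had 3974 and CD11b cells 618. Slfn1 (log2 change 2.17), Prc1 (2.14), the chemokine receptor Cxcr4 (2.10), Dusp1 (2.09), Lrrn4 (2.05) and Tmem176b (2.02) also rose. Clip4 (-2.68), Gpr25 (-2.21), Dixdc1 (-2.18), Scel (-2.13), Tmem108 (-2.11) and Pdlim1 (-2.07) also fell. Among 21 inhibitory receptors Tigit and Lilrb4a (3.26-fold higher) rose, Cd96 fell and 18 did not pass. With p-values adjusted over the list alone, 3 rose and 1 fell (camera adjusted p = 0.0727). Of 25 ILC1-like markers, Tmem176b and Inpp4b (2.76-fold higher) rose, 0 fell and 23 did not pass. The median was 0.13, and adjusted over the list alone 8 rose and 2 fell (camera adjusted p = 0.00934; adjusted p = 0.201 with an estimated correlation). Without the 3 arrays of KO replicate 3 this list did not pass (median 0.07, camera adjusted p = 0.0601). Of 22 immature NK markers, Cxcr4 and Inpp4b rose, 0 fell and 20 did not pass, with a median of 0.01 and a mean of 0.33 (camera adjusted p = 0.00836; adjusted p = 0.262 with an estimated correlation). Adjusted over the list alone, 8 rose and 1 fell, and the median was -0.02 without CD11b WT replicate 3.

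Cell cycle genes had a median of 1.3 log2 in CD11b cells (camera adjusted p = 9.75e-15; adjusted p = 0.315 with an estimated correlation), with 0 of 53 called by limma and 4 that rose when adjusted over the list alone. Without KO replicate 3 in all subsets the median was 0.64 and 23 genes rose. Markers of other cell types were high on the same array. Lyz2, a gene of macrophages and neutrophils, read 12.27 on the CD11b array of KO replicate 3 and 7.96 on that of KO replicate 1, against at most 5.32 on WT CD11b arrays. Cd74 read 11.68 and 6.97 on these arrays, against at most 5.26. The list of neutrophil markers had a median of 1.16 (camera adjusted p = 7.55e-07; adjusted p = 0.315 with an estimated correlation), and that of dendritic cell and MHC class II markers 0.95 (9.59e-09; adjusted p = 0.262 with an estimated correlation). That of macrophage markers was 0.21 (camera adjusted p = 3.47e-07; adjusted p = 0.262 with an estimated correlation) and that of B cell markers 0.24 (2.24e-05; adjusted p = 0.262 with an estimated correlation), with 0 calls in each. Without CD11b KO replicate 3 these medians were 0.02, 0.14, 0.08 and 0.05. The dendritic cell and macrophage lists then still passed (camera adjusted p = 0.00478 and 0.0148), and the neutrophil and B cell lists did not (0.404 and 0.149).

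T cell markers, lower in CD27 KO cells, had a positive median of 0.16 over 16 genes in CD11b cells (camera adjusted p = 0.0191; adjusted p = 0.209 with an estimated correlation). Ubash3a rose (1.78-fold higher, adjusted p = 0.0111), 0 fell and 15 did not pass, with 1 rise when adjusted over the list alone. The Ubash3a call ended without CD11b WT replicate 1 or 2 (adjusted p up to 0.066). Without CD11b KO replicate 3 this list did not pass (camera adjusted p = 0.0697). Erythroid and platelet markers had a median of 0.06 (camera adjusted p = 0.00565), and mast cell and basophil markers 0.11 (0.00335), with 0 calls in each. Without CD11b KO replicate 3 neither passed (medians 0.04 and 0.05, camera adjusted p = 0.199 and 0.135). Interferon response genes had a median of 0.11 and 0 calls among 25 (0.000404), and cytokines and chemokines a median of 0.06 with 1 rise among 27 (0.0191). Without KO replicate 3 in all subsets the cytokine list did not pass (median 0.03, camera adjusted p = 0.0601), and the interferon list did (0.17, 0.000483). With CD11b KO replicate 3 alone left out, the cytokine list still passed (camera adjusted p = 0.0496). Adjusted over the list alone, 3 interferon response genes rose, and 4 cytokine genes rose and 1 fell. In CD11b cells 12 of the 23 lists passed with the preset correlation and 0 with an estimated correlation. With 1 array left out, the calls of Prc1 and Cxcr4 ended at adjusted p-values of up to 0.0688 and 0.177 (without CD11b KO replicate 3), those of Lrrn4, Tmem176b and Lilrb4a at 0.0732, 0.0666 and 0.124 (without CD11b WT replicate 2). The count was 182 without CD11b WT replicate 2, 1094 without CD11b KO replicate 2, and 34 when only the 2 groups compared were in the fit. The other 16 of the 20 genes named for their size kept their calls under each alternative run for them.

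The KO effect was also averaged over the 3 subsets. Cd81 was 9.45-fold higher (95% interval 7.22 to 12.4, adjusted p = 4.65e-07) and Clec4e 6.85-fold higher (5.75 to 8.17, adjusted p = 3.40e-08). Among the genes that fell were Clip4, 5.32-fold lower (4.47 to 6.33, adjusted p = 9.49e-08), and Kcnc1, 3.87-fold lower (3.28 to 4.56, adjusted p = 4.68e-07). Styk1 was 3.25-fold lower (2.69 to 3.93, adjusted p = 3.62e-06) and Ptpn3 3.24-fold lower (2.66 to 3.94, adjusted p = 4.64e-06). The largest average change was that of 1 of the 2 probe sets of the potassium channel Kcnma1, 21.3-fold higher (6.47 to 70.0, adjusted p = 0.00393). It did not pass in any single subset (adjusted p from 0.189 to 0.225), and the other Kcnma1 probe set did not pass in the average (log2 change 0.04, adjusted p = 0.664). The transcription factor gene Runx1, a paralog of Runx3, was 1.26-fold higher (1.14 to 1.39, adjusted p = 0.00695). Cbfb, which encodes their shared partner, did not pass (1.01-fold higher, adjusted p = 0.927). Of the regulators of NK cell development, Eomes was 1.14-fold lower (adjusted p = 0.0223) and Tbx21 (T-bet) did not pass (1.07-fold lower, adjusted p = 0.349).

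The average called 2862 probe sets, 992 higher and 1870 lower (590 and 1288 named genes). After cyclic loess 1320 of 2500 were higher and 1180 lower, so the excess of lower probe sets rests on the normalization. Because arrays of 1 sample in different subsets may not be independent, the count was 1587 with the sample as a random block, and 71 when the 3 arrays of a sample were first averaged and 3 samples were compared with 3. In the comparison of 3 samples with 3, Cd81 (adjusted p = 0.0313), Clec4e (0.000304), Clip4 (0.0139), Kcnc1 (0.0195), Styk1 (0.0487), Ptpn3 (0.0139), Gpr25 (0.0445), Cd226 (0.0139), Dusp1 (0.0195) and Tigit (0.0139) still passed. Runx3 (0.101), Runx1 (0.201), Eomes (0.295), Kcnma1 (0.259) and the cyclin gene Ccna2 (0.213) did not. Slc15a2 (log2 change -2.58), Cd72 (-2.54), Gata6 (-1.91), Mgll (-1.75) and Pdlim1 (-1.65) were further falls. The cyclin genes Ccna2 (3.52) and Ccnb2 (2.92), the mitotic genes Bub1 (2.73), Cenpe (2.62), Kif18b (2.61) and Nusap1 (2.54), and Sympk (2.39) were further rises. With 3 samples against 3 none of these passed, at adjusted p-values between 0.0575 (Pdlim1) and 0.378 (Bub1). The call of Cd72 ended without the 3 arrays of KO replicate 3 (adjusted p = 0.0649), and so did that of Eomes (0.0728). The Eomes call also ended without DP WT replicate 3 (adjusted p = 0.0510) and with the sample as a random block (0.0665). That of Itgam, 1.47-fold lower (adjusted p = 0.0365), ended with 14 of the 18 arrays left out in turn (adjusted p up to 0.0767).

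**Figure D2:**
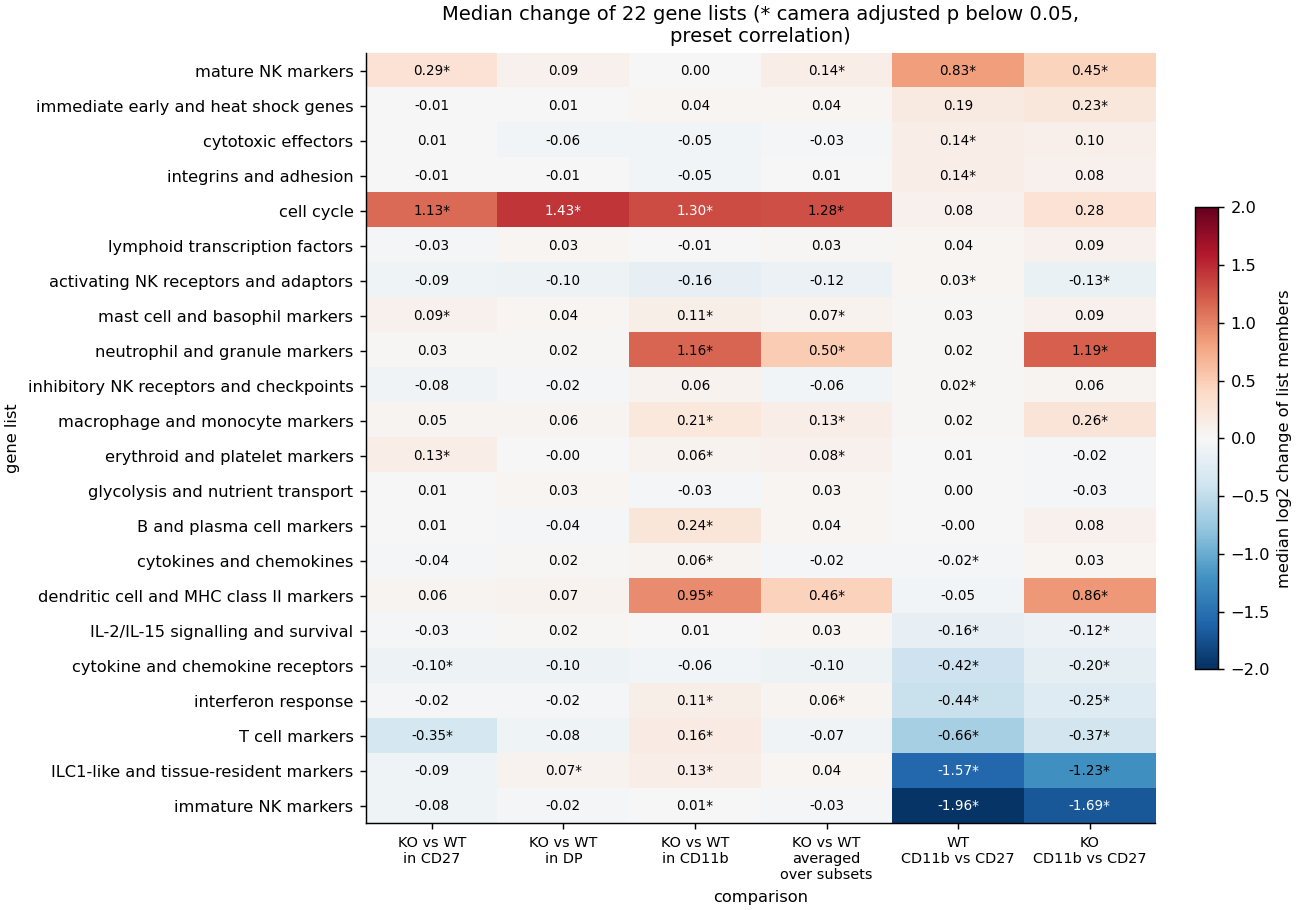
Median log2 change of the members of 22 gene lists (vertical axis) in 6 comparisons (horizontal axis); an asterisk marks a camera adjusted p below 0.05 with the preset correlation, whose direction can differ from that of the median. Cell cycle medians lie between 1.13 and 1.43 in the 4 comparisons of KO with WT, and immature NK markers have the lowest medians of the CD11b to CD27 comparisons, at -1.96 in WT and -1.69 in KO.

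Over the subsets, 22 of 53 cell cycle genes rose, 0 fell and 31 did not pass, with a median of 1.28 log2 (camera adjusted p = 2.14e-22; adjusted p = 0.607 with an estimated correlation), and 36 rose when adjusted over the list alone. Relative to the WT mean of the subset, the list's median was between 2.86 and 3.27 on the 3 arrays of KO replicate 3, between 0.23 and 0.77 on the 6 arrays of KO replicates 1 and 2, and between -0.06 and 0.05 on the WT arrays. Without KO replicate 3 the median was 0.49, with 32 genes that rose and 2 that fell. Of 24 mature NK markers 6 rose, Entpd1 (2.50-fold higher), the potassium channel Kcnj8 (5.24-fold higher) and the integrin chain Itgb7 (1.57-fold higher) included, 1 fell and 17 did not pass. With p-values adjusted over the list alone, 7 rose and 1 fell (median 0.14, camera adjusted p = 0.000560; adjusted p = 0.607 with an estimated correlation). Of 26 genes of interleukin-2 and interleukin-15 signalling, 5 rose, 3 fell and 18 did not pass, with 5 and 4 when adjusted over the list alone (camera adjusted p = 0.303). The feedback inhibitors Socs2 (2.99-fold higher) and Cish (1.49-fold higher) and the survival factor Bcl2 (1.51-fold higher) were among those that rose. Of 21 activating receptors and adaptors 2 rose, Cd226 (2.02-fold higher) among them, 7 fell, Crtam (2.76-fold lower) and Klra8 (1.87-fold lower) among them, and 12 did not pass. Adjusted over the list alone, 3 rose and 7 fell (camera adjusted p = 0.117). Of 31 cytokine and chemokine receptors 3 rose, Cxcr4 (2.83-fold higher) among them, 9 fell, Il18r1 (1.64-fold lower) and Ccr2 (1.59-fold lower) among them, and 19 did not pass. With p-values adjusted over the list alone, 4 rose and 13 fell (camera adjusted p = 0.303). Interferon response genes had 4 rises, Oas3 (2.47-fold higher) and Oasl2 (1.99-fold higher) among them, 0 falls and 21 that did not pass, with 6 rises when adjusted over the list alone (median 0.06, camera adjusted p = 0.0265; adjusted p = 0.607 with an estimated correlation). The median was -0.0031 without DP WT replicate 2 and -0.04 with Xist as a covariate, where the list did not pass (camera adjusted p = 0.390).

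Of the list members named above for their average change, Cd226 still passed when 3 samples were compared with 3. Among the others Socs2 (adjusted p = 0.141), Cish (0.0527), Bcl2 (0.208), Entpd1 (0.0992), Kcnj8 (0.298), Itgb7 (0.153) and Crtam (0.129) did not. The same holds for Klra8 (0.166), Cxcr4 (0.242), Il18r1 (0.0961), Ccr2 (0.0874), Oas3 (0.0645) and Oasl2 (0.280). Lists of other cell types passed in the average as well. The median was 0.50 for neutrophil markers (camera adjusted p = 0.00990), 0.46 for dendritic cell and MHC class II markers (0.00101) and 0.13 for macrophage markers (0.00331). It was 0.08 for erythroid and platelet markers (0.00879) and 0.07 for mast cell and basophil markers (0.00868). Of their members 1 macrophage and 1 mast cell gene rose, 0 fell, and adjusted over the list alone 1 macrophage gene rose. Each of these 5 lists had an adjusted p of 0.607 with an estimated correlation. Without the 3 arrays of KO replicate 3 the medians lay between 0.0022 and 0.05, and none of the 5 passed (camera adjusted p from 0.102 to 0.717). Without CD11b KO replicate 3 alone, the lists of dendritic cell (adjusted p = 0.00542), macrophage (0.0139) and mast cell markers (0.0317) still passed. Those of neutrophil (0.342) and erythroid markers (0.0540) did not. In all, 8 of the 23 lists passed in the average with the preset correlation and 0 with an estimated correlation.

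**Figure D3:**
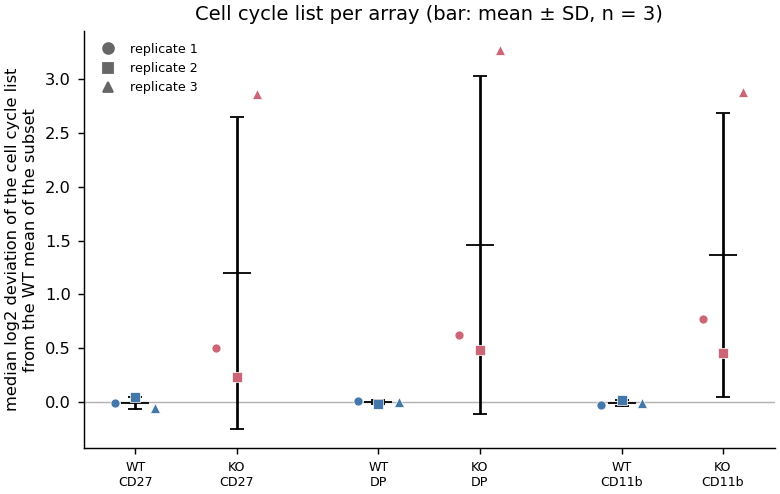
Median log2 deviation of the 53 cell cycle genes from the WT mean of the same subset (vertical axis) on each of the 18 arrays, with symbols for the replicate number and bars for the mean ± SD of 3 arrays. The arrays of KO replicate 3 lie between 2.86 and 3.27, those of KO replicates 1 and 2 between 0.23 and 0.77, and the WT arrays between -0.06 and 0.05.

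KO effects in the 3 subsets had correlations across genes of 0.819 (CD27 and DP), 0.657 (CD27 and CD11b) and 0.747 (DP and CD11b), genes not being independent replicates. Called in all 3 subsets were 17 genes that rose and 37 that fell. Within a genotype, residuals of arrays with the same replicate number correlated in 5 of the 6 pairs of subsets (r above 0.1 for each number), so samples shared between subsets would raise these correlations and overlaps. A difference of the KO effect between subsets was found for 4 genes by limma's F test (1478 probe sets at an unadjusted p under 0.05; 41 with a replicate block). Nuak1 (adjusted p = 1.81e-05) and Ndrg2 (adjusted p = 0.0123), 2 genes that were high in WT CD11b cells, fell by 3.25 and 1.82 on the log2 scale in CD11b cells and had changes of -0.16 and -0.25 in CD27 cells. Dscam (adjusted p = 0.00374), highest in WT CD27 cells, fell by 2.27 in CD27 cells and had a change of -0.08 in CD11b cells. Where Nuak1 and Dscam changed little, their WT levels were low and left little room for a measurable fall. WT means were 5.17 in CD27 and 5.49 in DP cells for Nuak1 and 5.29 in DP and 4.99 in CD11b cells for Dscam, with at most 35.6% of probe sets lower (Nuak1 in DP cells). Ndrg2 lay nearer the middle, at 6.28 and 6.51 in WT CD27 and DP cells (49.4% and 52.2% of probe sets lower), against 8.97 in WT CD11b cells. The next genes by this test, Marcks, Tnfaip8, Avil, Itgb4 and Cdhr1, did not pass (adjusted p = 0.0929 for each), nor did Dixdc1 (0.133). For a gene that this test did not call, a call in 1 subset and not in another does not by itself show that the KO effect differed.

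Maturation of WT cells was examined as a reference, since the labels call CD27 cells immature and DP and CD11b cells mature. From CD27 to CD11b cells the chemokine receptor Cx3cr1 rose 18-fold (95% interval 8.15 to 39.8, adjusted p = 0.000342). Gpx8 rose 14.9-fold (10.1 to 22.1, adjusted p = 1.24e-06) and the sialomucin Podxl 10.8-fold (8.42 to 13.8, adjusted p = 7.18e-08). The interleukin-7 receptor gene Il7r was 47.9-fold lower (24.4 to 93.8, adjusted p = 7.52e-06) and the chemokine receptor Cxcr3 11.9-fold lower (8.39 to 16.8, adjusted p = 1.10e-06). The chemokine Xcl1 was 11.4-fold lower (8.0 to 16.2, adjusted p = 1.26e-06) and the cytokine receptor Kit 11.1-fold lower (4.53 to 27.3, adjusted p = 0.00338). Tbx21 rose 1.40-fold (adjusted p = 0.00747), and Runx3 did not pass (1.24-fold higher, adjusted p = 0.138).

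Between WT CD11b and CD27 cells 1771 probe sets passed, 1018 higher and 753 lower in CD11b cells (752 and 506 named genes; 3865 with a replicate block). Anxa8 (log2 change 3.95), Cbr2 (3.64), Top1mt (3.60), Nuak1 (3.43), Fam81a (3.27), Rhpn1 (2.73) and Ndrg2 (2.68) also rose. Emb (-4.64), Cd3e (-4.43), Gpr183 (-4.24), Cd3d (-3.99), Ltb (-3.75) and Cxcr6 (-3.49) also fell. All 20 genes named for the size of their change kept their calls under each alternative run for them, and the lowest count with 1 array left out was 1052 (without CD11b WT replicate 1).

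Of 22 immature NK markers 15 fell, 0 rose and 7 did not pass (median -1.96, camera adjusted p = 1.17e-32), and 19 fell when adjusted over the list alone. Of 25 ILC1-like markers 16 fell, 0 rose and 9 did not pass, with 3 rises and 17 falls when adjusted over the list alone (median -1.57, camera adjusted p = 3.56e-23). Of 24 mature NK markers 15 rose, Cx3cr1, Cma1 (6.25-fold higher) and Itgam, the gene of the sort marker CD11b, among them. Of the others 1 fell, St6galnac3 (4.33-fold lower), and 8 did not pass, with 17 and 2 when adjusted over the list alone (median 0.83, camera adjusted p = 2.80e-12). T cell markers had a median of -0.66 over 16 genes, of which 8 fell, 0 rose and 8 did not pass, with 10 falls when adjusted over the list alone (camera adjusted p = 7.99e-14). Cytokine and chemokine receptors fell in 12 and rose in 3 of 31 genes, 16 not passing, and in 15 and 7 when adjusted over the list alone (median -0.42, camera adjusted p = 1.50e-07). These 5 lists held with an estimated correlation, at adjusted p-values of 7.25e-05, 1.08e-05, 0.0405, 9.89e-05 and 0.0214. So did cytokines and chemokines (7 falls, 2 rises and 18 not passing of 27; 7 and 3 adjusted over the list alone; median -0.02; adjusted p = 0.0110), and interleukin-2 and interleukin-15 signalling (6 falls, 1 rise and 19 not passing of 26; 10 and 2 adjusted over the list alone; median -0.16; adjusted p = 0.0318). The sign of the cytokine median is not settled, since it was 0.0097 without CD27 WT replicate 2 and 0.011 without CD11b WT replicate 3.

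Cytotoxic effectors rose in 7 of 19 genes, Gzmb (4.89-fold higher) and Prf1, which encodes perforin (1.82-fold higher), among them, 1 fell, Gzmm (4.94-fold lower), and 11 did not pass, with 9 and 2 when adjusted over the list alone (median 0.14, camera adjusted p = 0.000940; adjusted p = 0.116 with an estimated correlation). Interferon response genes fell in 5 of 25, Rtp4 (2.77-fold lower) and Ifih1 (1.96-fold lower) among them, 1 rose and 19 did not pass, with 10 falls and 1 rise when adjusted over the list alone (median -0.44, camera adjusted p = 6.98e-08; adjusted p = 0.116 with an estimated correlation). Activating receptors had 6 falls, Slamf6 (9.02-fold lower) and Cd160 (6.45-fold lower) among them, 0 rises and 15 not passing of 21, with 7 falls and 1 rise adjusted over the list alone. The list's median was 0.03, its mean -0.56 and its camera direction down (adjusted p = 0.000347; adjusted p = 0.432 with an estimated correlation). The median was -0.05 without CD27 WT replicate 1, -0.00032 without CD27 WT replicate 2 and -0.02 without CD11b WT replicate 2. Inhibitory receptors had 4 falls, Lilrb4a (5.05-fold lower) and Cd200r1 (2.96-fold lower) among them, 1 rise and 16 not passing of 21, with 6 falls and 1 rise adjusted over the list alone. Here the median was 0.02, the mean -0.17 and the camera direction down (adjusted p = 0.0170, or 0.116 with an estimated correlation). With the replicate number as a fixed block the inhibitory receptors did not pass (camera adjusted p = 0.152). The median was -0.010 after cyclic loess and -0.03 without CD27 WT replicate 1.

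The steps of WT maturation were compared in turn. From CD27 to DP cells 197 probe sets passed, 77 higher and 120 lower in DP. Itgam, the gene of the sort marker CD11b, rose 4.67-fold (3.17 to 6.87, adjusted p = 0.00123), Gpx8 6.49-fold (adjusted p = 0.000236) and Gzmb 3.33-fold (adjusted p = 0.00184). Cd3e was 15.5-fold lower (adjusted p = 0.00380), Tmem176b 6.63-fold lower (adjusted p = 0.00272) and Xcl1 3.96-fold lower (adjusted p = 0.00141). From DP to CD11b cells 186 passed, 109 higher and 77 lower in CD11b (851 with a replicate block). Cbr2 rose 10.4-fold (adjusted p = 1.14e-06), Nuak1 8.63-fold (adjusted p = 1.26e-07) and Podxl 8.35-fold (adjusted p = 4.83e-07). Cxcr3 was 7.32-fold lower (adjusted p = 3.08e-05), Gpr183 6.95-fold lower (adjusted p = 0.000422) and Tigit 2.51-fold lower (adjusted p = 0.000759). Leaving out 1 array lowered these counts to 81 (without CD27 WT replicate 2) and 72 (without DP WT replicate 2).

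KO cells were compared in the same way to see whether maturation differences were present without Runx3. From KO CD27 to KO CD11b cells Podxl rose 8.0-fold (95% interval 6.24 to 10.3, adjusted p = 6.79e-07) and the chemokine Ccl9 7.18-fold (adjusted p = 1.45e-05). Itgam, the gene of the sort marker CD11b, rose 6.33-fold (4.30 to 9.32, adjusted p = 0.000108), a difference that the sort itself selects. Xcl1 was 13.0-fold lower (9.15 to 18.5, adjusted p = 2.30e-06), Il7r 18.2-fold lower (9.30 to 35.8, adjusted p = 0.000238) and Cxcr3 6.87-fold lower (4.85 to 9.72, adjusted p = 2.76e-05). Immature NK markers fell in 13 of 22 genes and rose in 0, with 9 not passing (18 falls adjusted over the list alone; median -1.69, camera adjusted p = 6.62e-31; adjusted p = 9.60e-05 with an estimated correlation). ILC1-like markers fell in 12 of 25 and rose in 0, with 13 not passing (16 falls and 3 rises adjusted over the list alone; median -1.23, camera adjusted p = 5.70e-21; adjusted p = 1.88e-05 with an estimated correlation). Mature NK markers rose in 9 of 24 genes, 1 fell and 14 did not pass (14 and 1 adjusted over the list alone; median 0.45, camera adjusted p = 1.61e-09; adjusted p = 0.0819 with an estimated correlation). Markers of some other cell types were higher in KO CD11b cells, while T cell markers were lower (median -0.37, camera adjusted p = 4.41e-06). T cell markers were also lower without CD11b KO replicate 3 (median -0.49, camera adjusted p = 5.34e-07). Lists of B cell, mast cell and erythroid markers did not pass (camera adjusted p = 0.113, 0.115 and 0.492). The median was 1.19 for neutrophil markers (camera adjusted p = 0.000598; adjusted p = 0.522 with an estimated correlation). For dendritic cell and MHC class II markers it was 0.86 (0.000598 and 0.463), and for macrophage markers 0.26 (0.000498 and 0.413). Without CD11b KO replicate 3 these medians were 0.05, 0.01 and 0.06, and the lists did not pass (camera adjusted p = 0.915, 0.984 and 0.452).

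Between KO CD11b and CD27 cells 734 probe sets passed, 441 higher and 293 lower (2185 with a replicate block; 377 without CD11b KO replicate 1 and 400 without CD27 KO replicate 1). Of the 1236 genes called in WT and 497 called in KO maturation, 377 were called in both and all 377 in the same direction, where chance gives 15.6. Of the 1236 genes, 94.9% had the same sign in KO, and across genes r was 0.684. Sign and r do not give the size of the changes. Over the 1236 genes the slope of the KO on the WT change was 0.62, a value that selecting genes by their WT calls can lower. Whether the change from CD27 to CD11b cells differed between genotypes was tested by the corresponding interaction, which called 13 probe sets (2132 at an unadjusted p under 0.05).

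Whether the KO effect resembles a shift along WT maturation was examined with DP arrays for the KO effect and the WT CD27 and CD11b arrays for maturation, so that no array served both. The samples may still be shared, since residuals of WT DP arrays correlated with those of same-numbered WT CD11b arrays (r of 0.386, 0.248 and 0.456). Across probe sets, which are not independent replicates, Pearson's r was 0.084. The 1018 probe sets higher in WT CD11b than CD27 cells had a median KO-WT change of -0.04 in DP cells (camera p = 0.30; p = 0.730 with an estimated correlation). The 753 lower ones had a median of -0.08 (camera p = 0.144; p = 0.508 with an estimated correlation). With 1 array left out, Pearson's r ran from -0.036 (without DP WT replicate 2) to 0.152 (without DP WT replicate 1, where the higher set had a median of 0.0084). It was 0.033 with probe sets above the median mean and 0.0054 with 1 probe set per gene.

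**Figure D4:**
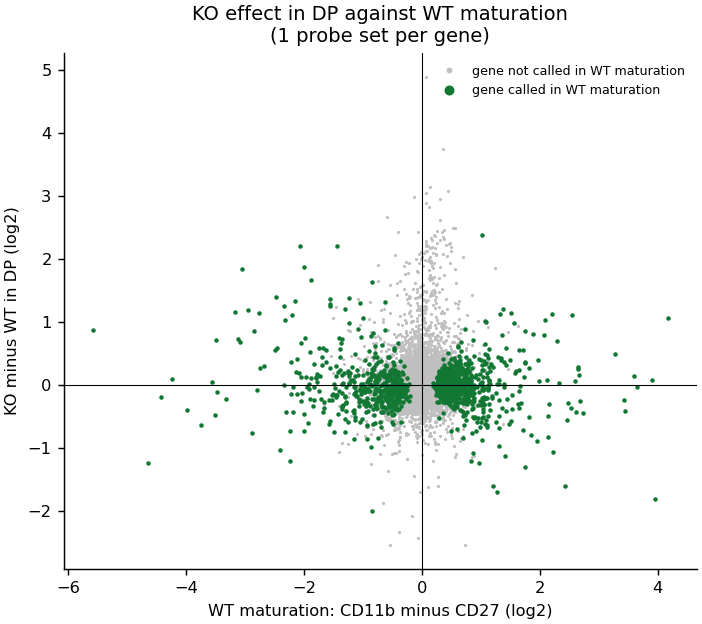
KO minus WT log2 change in DP cells (vertical axis) against the WT CD11b minus CD27 log2 change (horizontal axis), 1 point per gene, with genes called in WT maturation in green and the others in grey. The cloud has no slope to speak of; over all probe sets Pearson's r was 0.084.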

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

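The tests of the cell cycle pattern, for KO replicate 3, for sex and for other cell types, were chosen only after the result was seen, and the bounds of bootstrap resampling (10000 resamples of list members) used for the 4 list medians below were added after their values were seen. By the values alone 4 of 4 explanations would have been excluded, with the bounds 0 of 4. The bounds resample genes, which can vary together, and do not measure the spread between samples. The gaps between arrays in the cell cycle pattern were added last, with all values known.

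The interaction test passed for 4 genes, but for Nuak1 and Dscam the WT levels in the subsets with small changes were low (5.17 and 5.49 for Nuak1 in CD27 and DP, 5.29 and 4.99 for Dscam in DP and CD11b cells, with at most 35.6% of probe sets lower), which left little room for a measurable fall there. Nuak1 (adjusted p = 1.81e-05) had KO-WT changes of -0.16 in CD27, -0.42 in DP and -3.25 in CD11b cells, and lower values on 3 of 3 KO CD11b arrays. Ndrg2 (adjusted p = 0.0123) had -0.25, -0.26 and -1.82, and Dscam (adjusted p = 0.00374) had -2.27, -0.43 and -0.08. Arhgap5 (adjusted p = 0.0232) had -1.33, -0.28 and -0.11, with WT means of 5.82 in DP and 5.64 in CD11b cells (43.0% and 40.3% of probe sets lower) and KO means of 5.53 to 5.59 in the 3 subsets, so the room for a fall was small there too.

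Cell cycle genes had higher values in KO arrays, with sample means of 0.63, 0.39 and 3.00 log2 for KO replicates 1, 2 and 3. The 6 arrays of KO replicates 1 and 2, which may stem from only 2 samples, all lay above the highest WT array. The lowest of them lay 0.19 above the highest WT array, more than the range of 0.10 among the WT arrays. That range is kept small because WT arrays are part of the mean they are compared with. The limit was also set with these values known. The gap therefore describes these arrays and does not decide on KO replicate 3 as the whole cause. All 6 arrays had low Xist, and their gap to the highest WT array with low Xist was 0.22. This gap compares 2 KO samples with 1 WT sample, which gives no spread between WT samples, so it does not decide on sex. With Xist as a covariate the median was 1.62 (1.28 without). That value does not decide on sex either, since KO replicate 3, the only KO sample with high Xist, sets the slope on Xist. How much of the size rests on KO replicate 3 or on sex cannot be told apart: without that replicate the median was 0.49 (95% bounds 0.22 to 0.85, the limit set being 0.3; estimated-correlation camera adjusted p = 0.409), and it was 0.50 (0.24 to 0.85) among samples with low Xist (1 WT, 2 KO) and 2.98 among those with high Xist (2 WT, and KO replicate 3), of which WT replicate 2 and KO replicate 3 had an intermediate Y-linked signal and may be mixed. Abundant transcripts of other cell types were Cd79a, Lyz2, S100a8, Cd74 and Alas2. In KO replicates 1 and 2 they exceeded the highest WT array by at most 0.13 in CD27 and 0.14 in DP cells. This argues against cells rich in these transcripts there, but not against cells of other kinds. Other markers named in DP cells went both ways. Cd22 (log2 change 1.06), Ly86 (1.51) and Mcpt8 (0.70) were higher on each KO than on each WT array, and Fcrla (-0.12) and Cd68 (-0.54) were lower. In CD11b cells the largest excess was 2.64 (Lyz2, with Cd74 at 1.71), so other cells remain open there although the cells were sorted for NKp46. KO replicate 3 was not part of this test. Its Cd74 values given above exceeded those of the WT arrays in each subset, so other cells remain open for that replicate too. An effect of Runx3 on proliferation, the biological explanation the design offers, stays open and is a hypothesis.

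CD3 transcripts were higher in WT than KO CD27 arrays, with a median KO-WT change of -1.32 over the CD3 genes. T cells in the WT sort are a candidate explanation, although the sort for NKp46 would remove ordinary T cells: the other 12 T cell markers, of which 0 passed by limma, had a median of -0.28 (bounds -0.47 to -0.07), a ratio of 0.21 to the CD3 genes; a ratio under 0.25 would have argued against T cells, but the bounds reach beyond that limit, so they cannot be told apart. Of the 12 other markers 5 are above the median of all probe sets in WT CD27 cells (9 of all 16). Fewer ILC1-like cells in KO cannot be told apart either, with a list median of -0.085 (bounds -0.35 to 0.14), 17 of the list's 25 genes being shared with other lists. A loss of CD3 expression from NK cells themselves was not tested.

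Calls near Runx3 could reflect a chromosome segment inherited with the KO allele. Of 200 genes, the 100 measured genes on each side of Runx3, 19 (9.5%) were called in the averaged comparison, against 9.22% of other genes (odds ratio 1.03, 95% interval 0.607 to 1.67, Fisher exact p = 0.902), which argues against a segment that raises the share of calls 2 times or more. A segment with changes in only a few genes was not tested.

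The number of calls was compared with the other splits of the samples into 3 and 3. There are 10 splits, too few for a share under 0.05. In each comparison 1 split, the real one, gave as many calls. Every other split mixes the compared groups, so a real difference adds to its spread and lowers its count. The other counts are therefore not those of data without a difference. The real count and the highest other were 321 and 7 in CD27, 140 and 0 in DP, 457 and 1 in CD11b, 2862 and 92 for the average, 197 and 87 for WT DP against CD27, 186 and 0 for WT CD11b against DP, 1771 and 0 for WT CD11b against CD27, 734 and 1 for KO CD11b against CD27, and 4 and 0 for the interaction. Where the replicate numbers pair the arrays, the highest count among splits that part all 3 pairs was 0 for WT CD11b against DP, WT CD11b against CD27 and KO CD11b against CD27.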

How the results depend on the processing

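Xist as a covariate, leaving out KO replicate 3 and averaging the arrays of a sample were chosen only after the data were seen. With cyclic loess and with an intensity trend each of the 9 counts stayed within 1.5 times its value, but cyclic loess moved the share of higher probe sets from 28.3% to 46.3% in CD27, from 35.2% to 46.8% in CD11b and from 34.7% to 52.8% in the averaged comparison. The cause was not tested unless stated. Of 355 called results for named genes, 3979 of 4546 alternative values kept side and direction, 567 no longer passed and 0 had the opposite direction. Of the values of called gene lists 544 were the same, 130 no longer passed and 10 changed sign. With fry 21 of the 52 called list results still passed, T cell markers in CD27 cells (fry adjusted p = 0.0181) among them, and 31 did not. By fry sex-linked genes had the direction down in CD27 (adjusted p = 0.0181) and CD11b cells (0.0114), where camera did not pass them (0.539 and 0.371). Their changes were mixed: 4 and 3 of 8 genes were higher in KO, with medians of -0.17 and -0.25 and means of 0.18 and 0.37. Xist was not balanced between the genotypes, so sex of the samples cannot be told apart from a KO effect here. The called member was Ddx3x, 1.31-fold lower in CD27 and 1.37-fold lower in CD11b cells. The signal limits low values: with probe sets above the median mean the interaction called 1 and the maturation correlation was 0.033.

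With only the groups compared in the fit, and so fewer degrees of freedom, the counts were 14 (KO against WT in CD27), 17 (DP), 34 (CD11b), 5 (WT DP against CD27), 73 (WT CD11b against DP) and 146 (KO CD11b against CD27). Array weights gave 3974 (CD27; the array of CD27 KO replicate 1 had a weight of 6.24), 218 (DP), 458, 393 and 3725 (WT DP against CD27, CD11b against DP, CD11b against CD27), 2231 (KO CD11b against CD27) and 39 (interaction). With no moderation the counts were 210 (CD27), 93 (DP), 117 (WT CD11b against DP) and 2 (interaction). A 1.5-fold minimum, stricter by construction, gave 212 (CD27), 296 (CD11b), 594 (average) and 978 (WT CD11b against CD27). With 1 probe set per gene the interaction called 8 and the maturation correlation was 0.0054. With Xist as a covariate the counts were 285 (DP), 972 (CD11b), 4377 (average) and 9 (interaction). Sample means gave 71 for the average, with 4 residual degrees of freedom.

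For KO against WT, a fixed replicate block gave 526 (CD27), 274 (DP) and 802 (CD11b). There the block joined WT and KO arrays of the same number, which did not pair, so these counts rest on a pairing that the arrays did not show. A fixed block of genotype and number together gave 694, 851 and 3865 (WT DP against CD27, CD11b against DP, CD11b against CD27). It gave 2185 for KO CD11b against CD27 and 41 for the interaction. A random block (correlation 0.206) gave 1587 (average), 397, 489 and 3012 (the same WT comparisons), 1506 (KO) and 21 (interaction). With the fixed block the WT CD11b against CD27 calls of inhibitory receptors (adjusted p = 0.152) and integrins (0.0623) were lost, as was that of ILC1-like markers for KO against WT in DP (0.118).

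Without KO replicate 3 in any subset the counts were 455 in CD27 (208 of them shared with the full fit), 197 in DP (98), 480 in CD11b (273), 2233 averaged (1658), 608 for KO CD11b against CD27 and 3 for the interaction (1).

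With 1 array left out the counts ranged from 117 to 282 (CD27), 46 to 199 (DP), 182 to 1094 (CD11b), 1959 to 3519 (average), 81 to 208 (WT DP against CD27), 72 to 222 (WT CD11b against DP), 1052 to 1415 (WT CD11b against CD27), 377 to 720 (KO CD11b against CD27) and 2 to 14 (interaction), and the maturation correlation from -0.036 to 0.15. By array, counts beyond 1.5 times were: CD27, without WT 2 117, WT 3 213, KO 1 160, KO 2 184; DP, WT 2 46, WT 3 63, KO 1 54, KO 3 81; CD11b, WT 1 301, WT 2 182, WT 3 263, KO 1 235, KO 2 1094, KO 3 255. For WT DP against CD27 they were: CD27 WT 2 81, CD27 WT 3 126, DP WT 1 88, DP WT 2 107, DP WT 3 104. For WT CD11b against DP: DP WT 2 72, DP WT 3 101, CD11b WT 1 100, CD11b WT 2 103, CD11b WT 3 75. For WT CD11b against CD27: CD27 WT 2 1121, CD27 WT 3 1125, CD11b WT 1 1052, CD11b WT 2 1092. For KO CD11b against CD27: CD27 KO 1 400, CD11b KO 1 377. For the interaction: CD27 WT 1 10, CD27 WT 3 14, CD11b WT 1 10, CD11b WT 2 2.

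List medians that changed sign, all near 0, were, in WT CD11b against CD27, inhibitory receptors (-0.010 with cyclic loess, -0.027 without CD27 WT replicate 1), activating receptors (-0.055 without CD27 WT 1, -0.00032 without CD27 WT 2, -0.024 without CD11b WT 2) and cytokines and chemokines (0.0097 without CD27 WT 2, 0.011 without CD11b WT 3). In the averaged comparison interferon response genes had -0.0031 without DP WT 2 and -0.038 with Xist as a covariate, and immature NK markers in CD11b had -0.022 without CD11b WT 3. The maturation correlation was -0.036 without DP WT 2. With 1 array left out these medians ranged up to 0.12 (interferon, without DP KO 3), 0.068 and 0.075 (activating and inhibitory, without CD27 WT 3) and 0.19 (immature, without CD11b KO 1), and down to -0.070 (cytokines, without CD11b WT 2).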

Other observations

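Further gene groups changed in both directions in the comparison averaged over subsets. Of 31 integrins and adhesion molecules 7 rose, among them Itgb3 (log2 change 1.03, adjusted p = 0.000703) and Vcl, which encodes vinculin (0.79, adjusted p = 0.000304), 5 fell, among them Itgax, which encodes CD11c (-0.89, adjusted p = 0.0196), and 19 did not pass; adjusted over the list alone, 7 rose and 8 fell (camera adjusted p = 0.303). Of 44 lymphoid transcription factors 4 rose, among them Tox (0.61, adjusted p = 0.00311), Ahr, which encodes the aryl hydrocarbon receptor (0.57, adjusted p = 0.00272), and Prdm1 (0.55, adjusted p = 0.00305), 6 fell, Cbfa2t3 among them (-0.77, adjusted p = 0.00175), and 34 did not pass; adjusted over the list alone, 6 rose and 6 fell (camera adjusted p = 0.303). Of 27 cytokines and chemokines 4 rose, among them Il10 (1.51, adjusted p = 0.000321) and Ccl9 (0.73, adjusted p = 0.00346), 1 fell, Xcl1 (-0.61, adjusted p = 0.0144), and 22 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.284). Among 21 inhibitory receptors Tigit (1.39), Lilrb4a (1.29) and Cd200r1 (1.06) rose, Cd96 fell (-0.76) and 17 did not pass; adjusted over the list alone, 4 rose and 2 fell (camera adjusted p = 0.418). With sample means Tigit passed (adjusted p = 0.0139) and the other genes of this paragraph did not.

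Among the genes called in all 3 subsets, those below were chosen after their values were seen. Ramp1, a receptor activity-modifying protein gene, had changes of 1.24, 1.32 and 0.68 in CD27, DP and CD11b cells, the aquaporin gene Aqp9 1.0, 1.28 and 1.59, the prostaglandin receptor gene Ptger3 0.52, 0.90 and 0.71, the growth factor gene Fgf13 -1.30, -1.37 and -1.41, the ubiquitin ligase gene Nedd4l -1.22, -0.71 and -1.11, and the phosphoinositide kinase gene Pik3cb -0.84, -1.08 and -0.97.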
